A study of Mus musculus with 2 samples.

How the data were processed

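Total RNA of control and lincU-overexpressing mouse embryonic stem cells was amplified to biotin-labelled RNA and hybridised to Affymetrix 3' expression arrays, 1 array per group, per the labels' protocols. The deposited values are log2 signals, 1 per probe set and array. MAS5 and the affy package are named, without version, order or role, in the submitters' processing notes. The scaling target of the arrays is not given in the sources used here. That the values are on a log2 scale was read from their range, with maxima of 15.13 and 15.26 on the 2 arrays. The values reach down to exactly 0, for 37 probe sets on the control array and 43 on the overexpression array. Detection calls and scanner files were not used here, and the table held part of the probe sets of this array type, so genes outside it were not analysed here.

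Probe sets were named through the annotation table of the array platform, and symbols were updated through gene IDs with the RefSeq gene table of assembly GRCm38.p6. Apart from 64 control probe sets, 15273 probe sets had a single gene name, 501 had several and 1156 had none. Of those with a single name, 15252 matched the RefSeq table and 21 kept the array's symbol. Probe sets with several names or none were left out of the gene comparisons. Chromosome and gene order came from the same RefSeq table, and no coordinates are given because the build behind the array annotation is not given in the sources used here.

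The values were compared as deposited, with no further scaling. Values under the 25th percentile of an array's named probe sets, 5.73 on the control array and 5.65 on the overexpression array, were raised to it. A gene was represented by its probe set of highest mean signal. It was bright if the array with the higher signal was at or above its own median, 7.96 or 7.90, and dim otherwise. It was counted if it was bright and its log2 difference, overexpression minus control, was at least 1 or at most -1. A difference with 1 array at the floor is a bound. With 1 array per group no test, standard error or p-value was computed, and the number of arrays limits the precision.

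Each of 25 gene lists was described by the median log2 difference of its measured members and by the percentile of that median among 10000 random lists of the same size, matched on mean signal in 20 bins. A list stands outside the random range if its percentile is under 2.5 or over 97.5. This percentile describes 2 arrays and is not a test between conditions. The lists, the counting rules and the alternatives were fixed before the data were examined, apart from those described as chosen later.

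The genes named were fixed by rule. They were the 12 genes with the largest difference in each direction among those counted, provided that their other bright probe sets had the same sign, and leaving out Riken, Gm and LOC identifiers. To these were added up to 3 bright members per list with the largest difference, and Dusp9, Nanog, Pou5f1, Sox2, Klf4, Esrrb, Dusp6, Spry4, Egr1, Fgf5, Otx2, Sox1 and, where a probe set names it, lincU. Genes that bound chromosomal runs, and others so described, were chosen after their values were seen.

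Steps along chromosomes were searched for after the data were examined. For each chromosome, bright genes were put in order and divided once, with at least 15 genes on each side, where the squared distance between the mean differences of the sides, weighted by gene number, was largest. The result was set against 1000 shuffles of all genes over all positions. The added alternatives were the counts and lists without the genes of 3 runs, and with the median of a run subtracted from its genes.

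The alternatives fixed in advance were centring on the array median, quantile normalization, subtraction of a loess trend on mean signal, no floor, a floor at the 40th percentile and a pseudocount in place of the floor. Others were no brightness rule, brightness at the 75th percentile, the mean over a gene's probe sets, leaving out probe sets of shared or mixed type, a 1.5-fold threshold, and bright list members alone. For bright list members alone, the random lists were still drawn from all genes of matched signal. A gene near the threshold can be bright through its higher array alone, so these percentiles do not compare like with like. Probe sets of shared or mixed type were those whose names end in _s_at, _x_at or _a_at.

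The rules were tested on simulated arrays of 10313 genes, made from the control array with noise of the size seen between probe sets of a gene. Of genes changed by 1.5 on the log2 scale, in sets of 50 per direction, 98% were recovered, and of genes changed by 2.5, 100%. The changed genes were drawn from those of higher mean signal alone, so recovery of dim genes was not tested. None of 5316 bright unchanged genes was counted, but this noise, with an SD of 0.23, holds no variation between cultures. The measured differences of bright genes outside the chromosomal runs had an SD of 0.37. The simulation therefore does not give the share of false calls on the real arrays. Of 200 random lists of 14 genes, 6.5% lay outside the random range. Lists of 14 bright genes, with every member shifted by 0.4, were found in 100% of 50 draws, and lists with dim members were not tried. A step of 0.5 planted after gene 40 of chromosome 2 was placed after gene 41, with a size of 0.55. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.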

Results

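Gene expression was measured on 2 Affymetrix 3' expression arrays, 1 from control mouse embryonic stem cells and 1 from cells overexpressing lincU, a long noncoding RNA. Both cultures were of the same embryonic stem cell line, which carries a green fluorescent protein reporter at Sox1, grown on feeder cells in 15% serum with 1000 U/ml of leukaemia inhibitory factor (LIF). The feeder cells were removed before RNA was taken. Fibroblast markers still had signal, with Col3a1 at a log2 signal of 10.31 in control and 10.27 in overexpressing cells, so feeder RNA may be present. The table held log2 signals for 16994 probe sets, of which 15273 were named to a single gene, giving 10313 genes. The median log2 signal was 7.87 on the control array and 7.81 on the overexpression array. Each group had 1 array, so no difference below has a replicate check, and each describes these 2 arrays. The repeated measurements at hand were different probe sets of 1 gene. Over 1732 genes with several bright probe sets, the log2 difference between arrays varied between probe sets of a gene with an SD of 0.23. That SD was 0.30 in the dimmest group of these genes and 0.17 in the brightest group, and it holds no variation between cultures.

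The comparison of overexpressing with control cells asks which transcripts differ when lincU is raised, with naive pluripotency and ERK signalling as the study's named subjects. In the overexpressing cells, transcription factors of naive pluripotency had higher signals, with Tbx3 at a log2 difference of 0.92, Esrrb at 0.65 on 1 bright probe set and 0.17 on another, and Nanog at 0.57. Markers of the formative and primed epiblast were lower, including Cldn6 at -1.57 and the de novo DNA methyltransferase Dnmt3b at -0.83. Immediate early genes were lower as a group, with Fosb at -1.41 and Fos at -1.06. Stretches of neighbouring genes on chromosomes 14 and 6 also differed together, and 42 of the genes counted as higher lay in them. Nanog lay in the chromosome 6 stretch and stood at 0.19 with the median of that stretch subtracted. No probe set was named lincU in the annotation used here, so the level of the overexpressed RNA was not measured.

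Of 5609 genes bright enough to be compared, 86 were at least 2-fold higher and 73 at least 2-fold lower in the overexpressing cells. Of the bright genes, 88.7% lay within 1.5-fold, and the median log2 difference was 0.00. Hoxa10, a homeobox gene of the posterior Hoxa cluster, had the largest difference of the genes counted, with a log2 signal of 6.19 in control and 9.82 in overexpressing cells. The imprinted adaptor gene Grb10 was 5.24-fold higher, from 9.80 to 12.19, on the only bright one of its 3 probe sets, and its log2 difference was 1.75 when the 3 were averaged. AF067061 was 5.37-fold higher, on a probe set type that can bind several related transcripts. A2m, which encodes a protease inhibitor, was 4.74-fold higher, and Ldb3, a gene of the muscle Z-disc, 4.49-fold higher. Alg12, a mannosyltransferase gene of N-glycan assembly, was 3.87-fold higher and the deubiquitinase gene Usp17la 3.50-fold higher. Mapt, which encodes the microtubule-associated protein tau, had a log2 difference of 1.90 on 1 bright probe set, of 0.55 when its 3 probe sets were averaged and of 0.54 without those of shared or mixed type. Smim27, the kinase gene Zap70, Rusc2 and the phosphatase gene Ptpn20 stood at the floor in control cells. Their folds, of 6.31, 5.95, 4.84 and 4.59, therefore depend on where the floor is set. With no floor the log2 differences of Smim27 and Ptpn20 were 3.44 and 3.11. With the floor at the 40th percentile the 4 genes differed by 1.32, 1.23, 0.94 and 0.86, so that Rusc2 and Ptpn20 were no longer 2-fold higher. At that floor Hoxa10, A2m, Ldb3 and Alg12 differed by 2.76, 1.27, 1.27 and 0.997, the last also under 2-fold. With a pseudocount in place of the floor, Hoxa10, Zap70, Rusc2, A2m and Ldb3 differed by 2.92, 1.99, 1.54, 1.62 and 1.58. With probe sets averaged, Zap70, Ldb3 and Alg12 differed by 1.48, 1.08 and 1.10, and without probe sets of shared or mixed type Rusc2 differed by 1.31.

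Among the genes with lower signal, Car4, which encodes a membrane-bound carbonic anhydrase, had a log2 difference of -2.24. Sfmbt2, an imprinted polycomb-group gene, went from 11.83 in control to 9.75 in overexpressing cells, a difference of -2.08. Cdx2, the transcription factor of the trophoblast lineage, differed by -1.89. The interferon-inducible guanylate-binding protein genes Gbp2 and Gbp2b differed by -1.89 and -1.75. Aass, an enzyme gene of lysine breakdown, differed by -1.84, Calml4 by -1.80 and Prom1, which encodes the surface glycoprotein CD133, by -1.78. Efs, Smoc1, the neurofilament gene Nefl and the casein gene Csn3 differed by -1.77, -1.73, -1.70 and -1.65. Of the 24 genes with the largest differences in the 2 directions, Ldb3, Ptpn20, Efs and Nefl lay on chromosome 14 and A2m on the distal part of chromosome 6. With the medians of the chromosome 14 runs given below subtracted, Ldb3, Ptpn20, Efs and Nefl stood at 1.09, 1.12, -1.18 and -1.11.

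**Figure D1:**
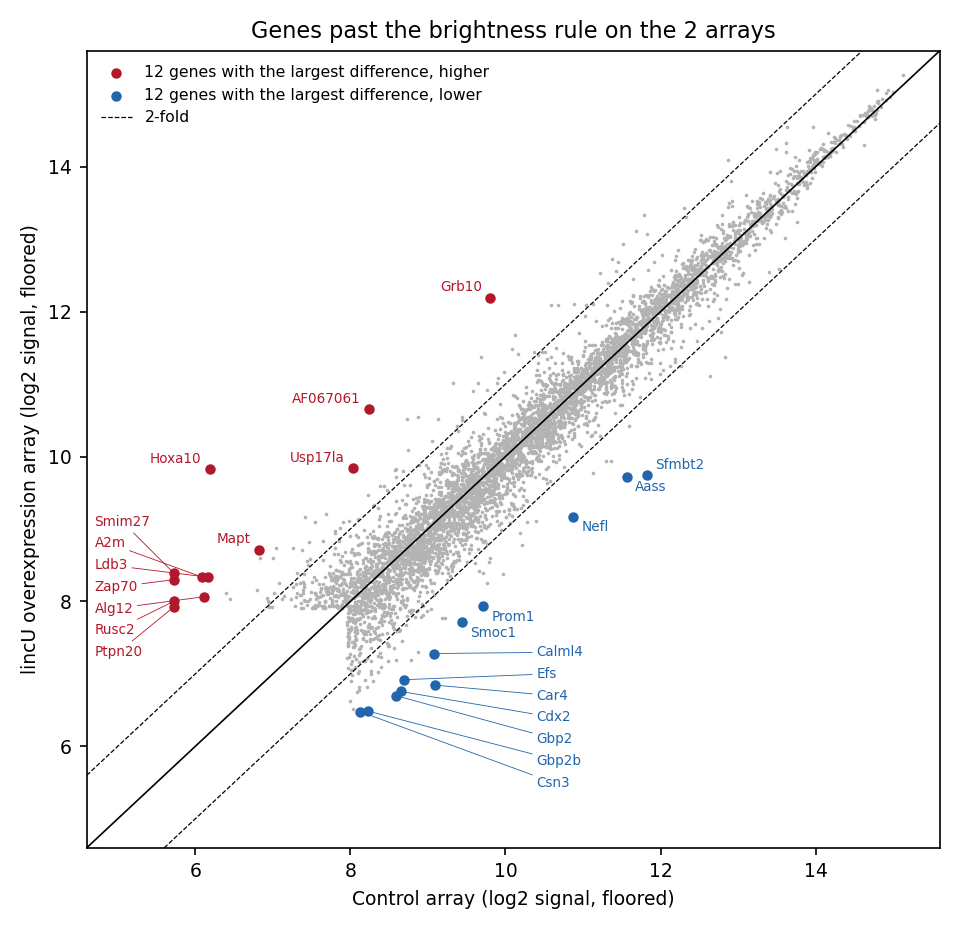
Each point is 1 of the 5609 bright genes, with its log2 signal on the control array (horizontal axis) and on the lincU overexpression array (vertical axis), after values under each array's floor were raised to it. Dashed lines mark a 2-fold difference, and the 12 named genes with the largest differences in each direction are coloured, from Hoxa10 at 3.63 to Car4 at -2.24.

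Genes of chromosome 14 differed by position, a pattern searched for after the data were examined. Gene order was taken from assembly GRCm38.p6. The 70 bright genes from Abhd6 to Ghitm had a median log2 difference of 1.08, and 63 of them were higher in overexpressing cells. Among them, 8 neighbouring genes from Thoc7 to Ube2e2 had a median of -0.30. The 137 bright genes from Tspan14 to Tmtc4, on the rest of the chromosome, had a median of -0.59, and 130 of them were lower. On chromosome 6, the 97 bright genes from Rad18 to Resf1 had a median of 0.37, against 0.02 for the 178 bright genes before them. The 5296 bright genes with a position on the autosomes or X outside these 3 runs had a median of 0.00. Chromosome 14 held 39 of the 86 genes counted as higher and 11 of the 73 counted as lower. Without all genes of the 3 runs, 5305 bright genes were left, including those without such a position. Of these, 44 were at least 2-fold higher and 62 at least 2-fold lower.

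**Figure D2:**
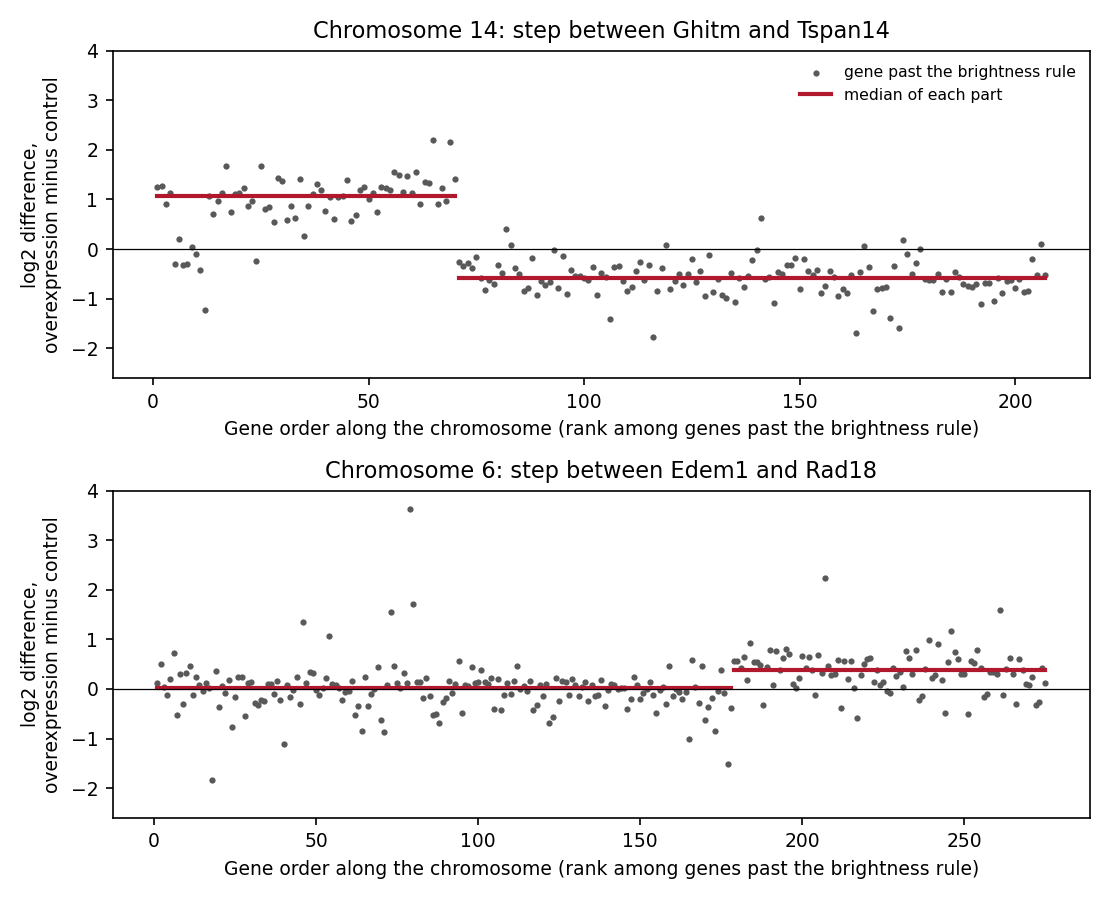
Each point is the log2 difference (lincU overexpression minus control) of 1 bright gene, placed by its rank along chromosome 14 (top) or chromosome 6 (bottom), and red lines are the medians of the 2 parts of each chromosome. On chromosome 14 the median goes from 1.08 up to Ghitm to -0.59 from Tspan14 on, and on chromosome 6 it goes from 0.02 to 0.37 at Rad18.

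Of 25 gene lists fixed before the data were examined, 11 had a median outside the central 95% of 10000 random lists of matched size and signal. For lists of independently drawn genes, 1.25 would be outside by chance. Some lists share genes, and members of a list may vary together. How many lists would lie outside between cultures of the same kind is therefore not known, with 1 array per group. The naive pluripotency list had a median log2 difference of 0.32, at percentile 100 of the random lists. Of its 14 members, all bright, 11 were higher. Besides Tbx3, Esrrb and Nanog, they included Tcl1, a coactivator of AKT, at 0.61 and Klf4 at 0.28. Of the 3 lower members Dppa3, picked after its value was seen, differed most, at -0.38. Nanog and Dppa3 lay in the chromosome 6 run, whose own median was 0.37, and with that median subtracted Nanog stood at 0.19. The core pluripotency list, which holds genes shared by naive and primed cells, was inside the random range with a median of 0.01. There, Pou5f1 differed by -0.21, Sox2 by 0.18, Lin28a by -0.53 on 1 bright probe set and -1.45 on another, Utf1 by -0.43 and Dppa2 by 0.35.

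The formative and primed epiblast list had a median of -0.53, at percentile 0, and 10 of its 12 bright members were lower. Besides Cldn6 and Dnmt3b, the transcription factor genes Sall2 and Otx2 differed by -0.92 and -0.39. Sall2, Otx2 and a further pair of measured members lay in the second part of chromosome 14, whose median was -0.59, and with that median subtracted Sall2 and Otx2 stood at -0.33 and 0.20. Without the genes of the runs, the 9 remaining members had a median of -0.53, at percentile 0.05, and with run medians subtracted the list's median was -0.30, at percentile 1.13. Fgf5, a marker of the primed epiblast, was under the floor on both arrays, at log2 signals of 5.59 in control and 2.84 in overexpressing cells. The DNA methylation machinery, which shares Dnmt3a and Dnmt3b with this list, had a median of -0.19, at percentile 2.19. In it Dnmt3a differed by -0.56, with its 4 bright probe sets between -0.92 and -0.45, and Dnmt3l by -0.30. Without probe sets of shared or mixed type its percentile was 18.5, but only 3 of its 6 members were left. Dnmt3b and Dnmt3l were among those dropped.

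**Figure D3:**
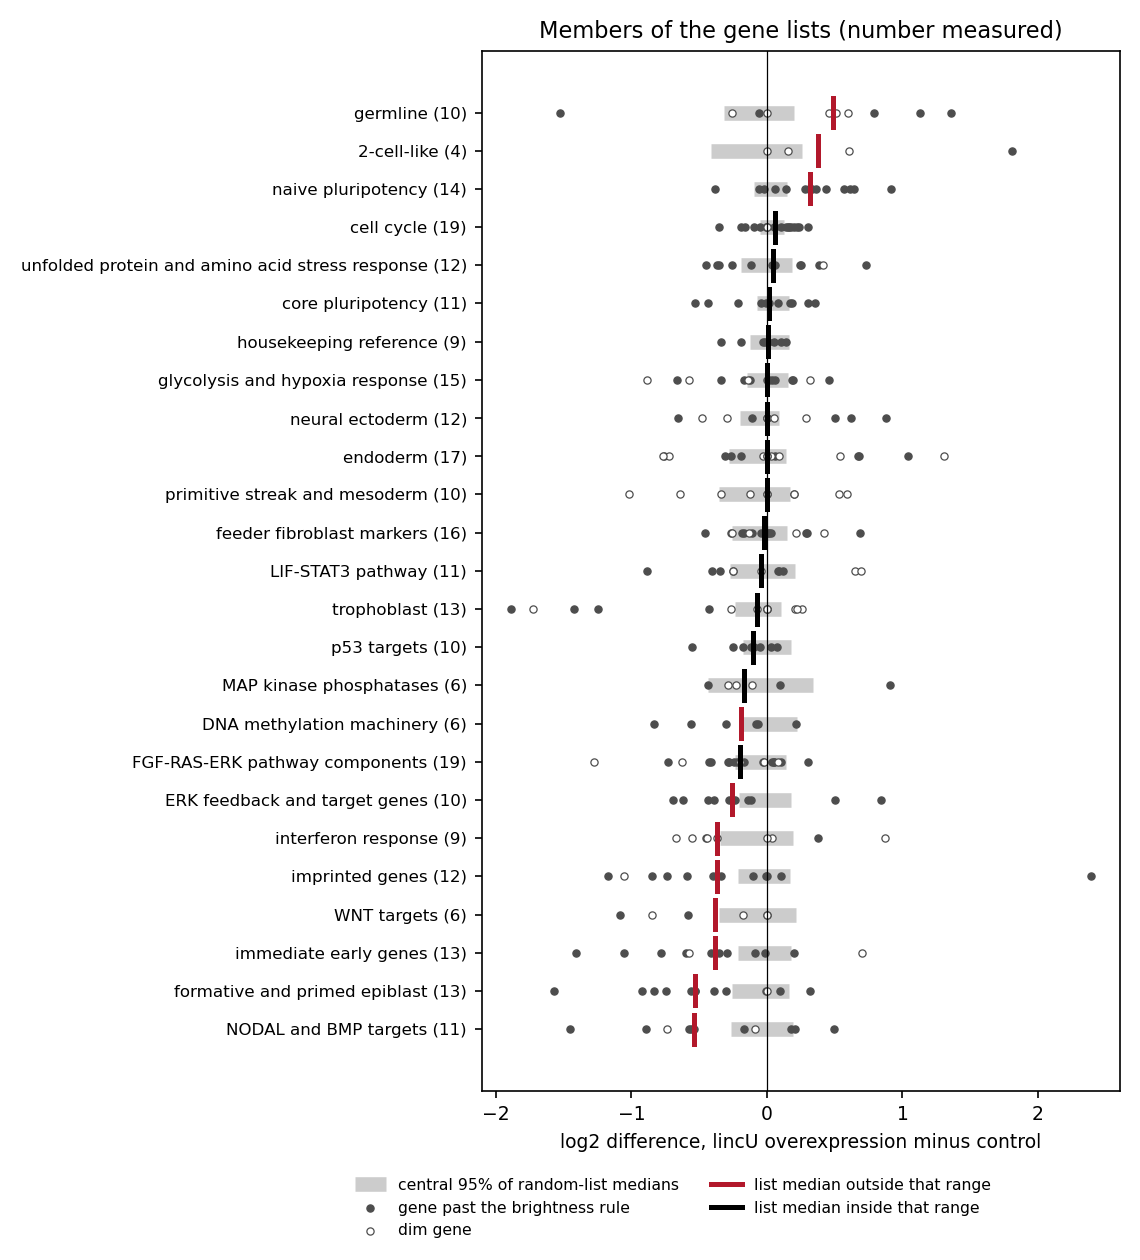
Each row is 1 gene list, each point 1 measured member's log2 difference (lincU overexpression minus control), filled where the gene was bright and open where it was dim; the vertical bar is the list median and the grey band the central 95% of medians of 10000 random lists. Medians outside the band are red, from -0.54 for NODAL and BMP targets to 0.48 for the germline list.

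Most measured members of 2 lists of transcripts that respond to ERK signalling were lower. Some of them differed by less than the SD of 0.23 between probe sets of a gene. The immediate early gene list had a median of -0.38, at percentile 0.045, and 10 of its 11 bright members were lower. Besides the AP-1 subunit genes Fosb and Fos, they included Srf, the serum response factor, at -0.78 and -0.33 on its 2 bright probe sets, and Egr1 at -0.29. The list of ERK feedback and target genes had a median of -0.26, at percentile 0.80, with 8 of 10 members lower. The feedback inhibitor genes Spry2 and Spred1 differed by -0.69 and -0.62, and Dusp6, which encodes an ERK phosphatase, by -0.43. Spry4, a feedback inhibitor gene of the same family as Spry2, went the other way, at 0.84 and 0.43 on its 2 bright probe sets. Etv4, a further member, was also higher, at 0.50. Spry2 lay in the second part of chromosome 14, and with the median of its run subtracted it stood at -0.099 and the list's percentile was 2.83. With probe sets of a gene averaged, that percentile was 3.62. Both of these percentiles lie inside the random range.

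The MAP kinase phosphatases as a list had a median of -0.17, at percentile 22.1. With its 3 bright members alone the median was 0.096, at percentile 70.9. Dusp9, an ERK phosphatase gene, had a log2 signal of 11.37 in control and 11.46 in overexpressing cells, a difference of 0.10. Dusp16, whose product acts on JNK and p38, differed by 0.91 and lay in the chromosome 6 run. Components of the FGF-RAS-ERK pathway had a median of -0.20, at percentile 4.75, inside the random range. The largest differences of its bright members were in the receptor gene Fgfr2 at -0.73, the phosphatase gene Ptpn11 at -0.42 and the kinase gene Rps6ka3 at -0.42.

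The list of NODAL and BMP targets had a median of -0.54, at percentile 0, with 6 of 9 bright members lower. Lefty1, which encodes a NODAL antagonist, differed by -1.45. The BMP-induced genes Id1 and Id2 differed by -0.89 and -0.57, and a second bright probe set of Id2 by -0.031. The list's median was -0.28 with the floor at the 40th percentile, -0.30 with probe sets averaged and 0.04 without probe sets of shared or mixed type. The last setting left 8 of its 11 members. WNT targets had a median of -0.38, at percentile 1.89, over 6 members of which 2 were bright. These were Tnfrsf19 at -1.09, which lay in the second part of chromosome 14 and stood at -0.49 with the median of that run subtracted, and Axin2 at -0.59. Without the genes of the runs the WNT percentile was 7.88. The LIF-STAT3 pathway was inside the random range at -0.05, with its feedback gene Socs2 at -0.88, Bcl3 at -0.41 and the kinase gene Pim1 at -0.35. With bright members alone the median of this list was -0.25, at percentile 2.31, outside that range. The random lists of this setting were not limited to bright genes.

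Lists of differentiated lineage markers had medians inside the random range, and most members were dim. A median of 0 in them falls on members under the floor on both arrays, whose difference was set to 0. The trophoblast list had a median of -0.07 and a mean of -0.49, at percentile 15.1, with 9 of 13 members dim. Its 4 bright members were all lower, among them Cdx2 and the epithelial keratin genes Krt8 and Krt18, at -1.43 and -1.25. With bright members alone its median was -1.34, at percentile 0. The random lists there were not limited to bright genes, and Cdx2 was bright through the control array alone. The neural ectoderm list had a median of 0, with Pax6 at 0.88, Nes at -0.66 and Tubb3 at 0.62. With bright members alone its median was 0.50, at percentile 99.8, again against random lists not limited to bright genes. Sox1, whose locus carries the line's reporter, was under the floor on both arrays, at 3.30 in control and 2.92 in overexpressing cells. The endoderm list had a median of 0, with the basement membrane genes Lama1 and Col4a1 at 1.04 and 0.68 and Amn at -0.76. In the primitive streak and mesoderm list, Eomes was the only bright member, and its 2 bright probe sets went opposite ways, at 0.20 and -0.35.

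The germline list had a median of 0.48, at percentile 99.98, over 10 members. Of these 5 were bright, 3 higher and 2 lower, and with the floor at the 40th percentile the median was 0.13, at percentile 99.7. Stra8, a gene of meiotic entry, differed by 1.36 and Dazl, which encodes a germ cell RNA-binding protein, by 1.13, while the X-linked homeobox gene Rhox5 differed by -1.53. The list of 2-cell-like genes had a median of 0.38, at percentile 99.5, over 4 members of which only Usp17la was bright. With the floor at the 40th percentile its median was 0. Imprinted genes had a median of -0.37, at percentile 0.06, and of -0.22 with the floor at the 40th percentile. Of the 11 bright members 8 were lower, including Peg3 at -1.17 and the noncoding RNA gene Meg3 at -0.85, while Grb10 was higher. Without probe sets of shared or mixed type Meg3 was left with 1 dim probe set, at 0.019.

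Feeder fibroblast markers, the other cell type the cultures held, had a median of -0.02, at percentile 59.7. Of their 12 bright members 6 were higher and 6 lower, with Pdgfrb at 0.69, Mmp2 at -0.46 and Prrx1 at 0.29. The first 2 of these changed direction without probe sets of shared or mixed type, Pdgfrb to -1.20 on a dim probe set and Mmp2 to 0.20. With probe sets averaged Pdgfrb stood at -0.15. The cell cycle list had a median of 0.06, with Ccna2 at 0.31, Mcm6 at 0.24 and Ccne1 at -0.35. The p53 targets had a median of -0.11, with Btg2 at -0.56 on 1 bright probe set and -0.050 on another, Pmaip1 at -0.25 and Perp at -0.18. The glycolysis and hypoxia response had a median of 0.00, with Vegfa at -0.66, Egln3 at 0.46 and Ero1a, in the second part of chromosome 14, at -0.34, or 0.25 with the median of that run subtracted. The unfolded protein and amino acid stress response had a median of 0.05, with the asparagine synthetase gene Asns at 0.73, Ddit3 at -0.45 and Xbp1 at 0.38, with its 4 bright probe sets between 0.0021 and 0.65. The interferon response had a median of -0.37, at percentile 1.71, but only Irf1 at -0.45 and Bst2 at 0.38 were bright, and with bright members alone the percentile was 55.6. The housekeeping reference genes had a median of 0.01, with Gusb at -0.34 on 1 bright probe set and -0.71 on another, Tbp at -0.19 and Rplp0 at 0.14. Without probe sets of shared or mixed type Tbp was left with 1 dim probe set, at 0.74.

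The hybridisation control RNAs had a median log2 difference of 0.10 over 18 probe sets, and the poly-A controls, added before labelling, one of 0.30 over 24 probe sets. The 4 poly-A controls differed from each other, with medians from 0.03 for lys to 0.53 for thr. The 3' minus 5' log2 signal of beta-actin was 0.45 in control and 0.50 in overexpressing cells, and that of Gapdh -0.31 and -0.32.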

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

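The test of heat shock genes, and that of naive and formative list membership in chromosomal runs, were laid out before their outcomes were seen. The runs had by then been found in the data. The tests of the runs themselves, of feeder share and of lincU overexpression were laid out after their outcomes were seen. Of the 1156 probe sets with no gene name, which no gene comparison used, 364 were bright, and 4 of these were at least 2-fold higher and 11 at least 2-fold lower in overexpressing cells. Of the 501 probe sets with several gene names, 319 were bright, and 7 were at least 2-fold higher and 10 at least 2-fold lower. As shares, 1.10% and 2.19% of these bright probe sets were higher, against 1.53% of bright genes, and 3.02% and 3.13% were lower, against 1.30%. They are given because they are signals outside the genes compared.

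The higher naive list and the lower formative list were set against membership in the chromosome 14 and 6 runs and against a different share of feeder fibroblasts. Without the genes of the runs, the formative list was still at percentile 0.05 and the naive list at percentile 100, and with run medians subtracted they were at 1.13 and 100, with the formative median at -0.30, which argues against membership in the runs as the whole cause. The feeder fibroblast markers were at percentile 59.7, and the 5 with the highest signal differed by at most 0.27, while Pdgfrb, less bright, differed by 0.69. A change in feeder share would also move naive and formative genes of the stem cells the same way, and these went apart, at 0.32 and -0.53. An effect of lincU, and a difference between cultures unrelated to it, may each lie behind the pattern and stay open, with 1 array per group.

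The lower immediate early genes were set against a harvest or heat stress difference between the 2 cultures and against lincU overexpression itself. A list of heat shock and dissociation stress genes written beforehand had a median log2 difference of -0.04, at percentile 9.05, over 12 bright members. The bound set in advance for excluding harvest stress was met, but it was a poor one, since 7 members were lower and 5 higher, with Klf6 at -0.83, Hspa1b at -0.36 and Hspb1 at 0.23. Harvest stress and lincU overexpression cannot be told apart here, because each condition was measured on 1 array.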

How the results depend on the processing

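The settings without the genes of the chromosomal runs, and with the run medians subtracted, were chosen after seeing the data. No paired analysis was possible because the groups share only replicate number 1, and no replicate could be left out. The cause of the shifts below was not tested unless the setting itself gives it. The naive, formative, immediate early, germline and imprinted lists kept their direction and stayed outside the random range in every setting run. Across the settings fixed in advance their medians ranged from 0.27 to 0.38, -0.53 to -0.45, -0.38 to -0.33, 0.13 to 0.79, and -0.37 to -0.22. The counts of genes at least 2-fold higher and lower, 86 and 73, became 155 and 230 with no brightness filter, 37 and 15 with brightness at the 75th percentile, and 261 and 375 at a 1.5-fold threshold. The higher count was 44 without the genes of the runs and 50 with run medians subtracted. Median centring gave 96 and 64, quantile normalization 96 and 63, and loess 97 and 62. Without mixed probe sets the NODAL and BMP targets went from -0.54 to 0.044, the interferon response to 0 and the DNA methylation machinery to -0.077. That setting left 8 of 11, 7 of 9 and 3 of 6 members of these lists. With no floor the neural ectoderm list was at 0.39 and the trophoblast list at -1.25, both then outside the random range, and the interferon response was at -0.55, inside it. With the floor at the 40th percentile the WNT targets were at -0.089, and the 2-cell-like and interferon lists at 0, which the setting gives by raising dim members to the floor. With the pseudocount the trophoblast list was at -0.55, outside, and the interferon response at -0.42, inside. With the mean over probe sets, ERK feedback genes were at -0.19, WNT targets at -0.24 and DNA methylation genes at -0.16, all inside. With bright members alone, the LIF-STAT3 pathway was at -0.25, the neural list at 0.50 and the trophoblast list at -1.34, all outside, and the interferon response at -0.036, inside. That setting did not limit the random lists to bright genes. Without the genes of the runs, WNT targets were at -0.18 and the interferon response at -0.18, both inside. With run medians subtracted, the formative list was at -0.30, outside, and ERK feedback genes were at -0.19 and WNT targets at -0.34, both inside. Of the values of single named genes under the alternatives, 902 moved by less than 1.5-fold and 38 by more. The brightness filter does not enter the list medians. For the control probe sets only median centring was run, giving 0.18 against 0.12, since the other settings are defined on named genes. Signal over background limits dim genes most: 4704 of the 10313 genes were below the brightness rule.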

Other observations

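The genes and families singled out here were chosen after their values were seen, as were the tests of the chromosome runs. Of 16 claudin genes measured, 3 were bright, and all 3 were lower: Cldn7 at a log2 difference of -1.58, Cldn6 at -1.57 and Cldn4 at -0.70. Of 32 keratin genes, Krt8 and Krt18 were the 2 that were bright, and Krt19, dim, differed by -1.73. Of 3 further genes looked up, Cdh1, which encodes E-cadherin, differed by -0.02, Epcam by -0.21 and Tjp1 by 0.01. Hoxa10 and its neighbour Hoxa11, at 1.72, were the only bright ones of 19 Hox genes measured. Of 6 guanylate-binding protein genes, the bright ones were Gbp2 and Gbp2b, and Gbp7, dim, differed by -1.40. Cldn6, Cldn7, Gbp2 and Gbp2b passed the brightness rule through the control array alone. Hoxa10 and Hoxa11 passed it through the overexpression array alone. The direction of these genes was thus tied to passing the rule, and their shared direction is no evidence about their families. Aire, the autoimmune regulator gene, differed by 1.76, and Foxd3, a transcription factor gene of pluripotent cells, by 1.03.

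The chromosome 14 run put genes of unrelated function side by side. In its first part, the chromatin genes Bap1 and Pbrm1 differed by 1.55 and 1.25, the JNK1 gene Mapk8 by 1.32, the glutamate dehydrogenase gene Glud1 by 1.22 and Parg by 1.35. The bright probe sets of Mapk8 ranged from 1.23 to 1.35. Within that part, the 8 bright genes from Thoc7 to Ube2e2 had a median of -0.30, while the 4 before them and the 58 after them had medians of 1.19 and 1.12. In the second part, Rcbtb2 differed by -1.59, Slc7a7 by -1.42 and Dok2 by -1.39, all below its lower quartile of -0.79. Rb1, at 0.19, was 1 of the 7 bright genes there that went the other way. The brighter and dimmer genes of each run shifted alike, with medians of 0.98 and 1.12 in the first part of chromosome 14, -0.59 and -0.58 in the second, and 0.40 and 0.33 on chromosome 6.

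The chromosome 14 and 6 runs were set against a chance order of unrelated genes, a brightness-dependent bias between the arrays, and a different copy number of these segments in the 2 cell populations. Of 1000 shuffles of gene positions, 0 gave a step as strong as the weaker one, on chromosome 6, and subtracting the loess trend on signal left the chromosome 14 step at -1.65 against -1.67, so the tables argue against both. A different copy number may account for the runs: their medians of 1.08 and -0.59 lie near 1, the log2 ratio of 4 copies over 2, and -0.58, that of 2 copies over 3. These ratios take 2 copies in control for the first part of chromosome 14 and 3 for the second. The explanation stays open because DNA was not measured here. A bound of over 90% of bright genes on their side of 0 was missed by 2 runs. The first part of chromosome 14 had 90% and the chromosome 6 run 83.5%. This bound cannot decide the question, because a shift that is small against the spread leaves many genes on the other side. On chromosome 6 the median of 0.37 came with an SD of 0.42. In the first part of chromosome 14, 6 of the 7 lower genes were among the 8 from Thoc7 to Ube2e2, whose median was -0.30. The chromosome 6 median lay below the 0.58 of 3 copies over 2. An effect of lincU on these regions was not separated from a difference between the cell populations that were compared.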
